A study of Rattus norvegicus with 8 samples.

How the data were processed

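Polyadenylated RNA of neonatal rat ventricular cardiomyocytes was measured by RNA-seq in 8 libraries: 3 given vehicle, 2 given phenylephrine (PE) and 3 given a miR-9 mimic and then PE. Per the labels' protocols, cells on gelatin-coated dishes received a control or miR-9 mimic at 25 nM, were washed 24 h later, and were stimulated with 10 µM PE or vehicle for 48 h. Groups were taken from each sample's treatment label. That label does not say which cultures without miR-9 had the control mimic. A stranded poly(A) mRNA kit was used, per the labels, so mature microRNAs were not measured and a microRNA gene's value reflects longer transcripts.

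The authors deposited 1 table of FPKM values, fragments scaled for transcript length and library size, and these were used as deposited. TopHat2, Cufflinks and the rat build rn4 are named per the submitters' processing notes, without tool versions. The annotation, the strand setting, any scaling beyond FPKM and the assignment of reads that map to several places are not given in the sources used here. Values of genes with near-identical copies are therefore uncertain. Among those named, these are the RT1 and ribosomal protein genes, the Ifit, Oas and Mx families, Hist1h1d, Myh6 and Myh7, and the actin genes. The same holds for microRNA genes, which often lie inside longer transcripts or near other genes. The table has 16900 entries, 92 for ERCC spike-ins and 16808 for gene symbols, without positions. In a table of rat genes on assembly GRCr8, used only for names, 14001 symbols matched a current symbol, 2369 only a synonym and 438 neither. FPKM tables hold no counts, so the absolute depth is unknown and no counting interval is given. Many low values share steps, taken here as the worth of 1 fragment. Over genes between 0.001 and 0.06 FPKM, the commonest ratio to Vehicle replicate 1, held by 130 to 169 of the 364 to 469 genes compared per library, gave relative depths of 0.905 to 1.49. A value of 0 makes up 19.7% of all gene values and can be a failed estimate as well as an absence of fragments.

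Genes with an FPKM of at least 1 in at least 2 libraries were tested, 10537 in all. Of the 6271 left out, 2345 were listed at 0 in every library. Values were taken as log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a mean-variance trend) fitted 1 mean per group over all 8 libraries, with a shared spread on 5 residual degrees of freedom. Tests were two-sided and adjusted by Benjamini-Hochberg over tested genes. Genes with an adjusted p under 0.05 are called, and errors of log2 fold changes are standard errors. Gene lists were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists of 1 comparison, and again with the correlation estimated from the residuals. fry, which asks whether a list's genes move on balance one way without setting them against other genes, was a further alternative. The design, the gene lists and the rule for named genes were fixed before the data were examined. There were 27 such lists with 541 genes, 53 of them not in the table. Erythroid markers had no tested member, so 26 lists were tested. A further 3 lists, of ribosomal proteins, antigen presentation and complement, were written after the data were seen. Within each list, calls were also adjusted over the list alone.

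The rule for named genes took, per comparison, the 10 highest and 10 lowest log2 fold changes among called genes whose group values do not overlap and whose symbol occurs once. It added Brd4, Brd2, Brd3, Nppa, Nppb, Myh6, Myh7, Acta1, Rcan1, Ankrd1, Xirp2, Serpine1, Ctgf, Postn and Atp2a2, and up to 4 called members of each described list with the largest absolute change, or 2 where none was called. The text takes the first of these in rule order and names other genes only as chosen after their values were seen. The overlap of the PE and miR-9 changes was set against 100 simulated draws that share the PE libraries, once with no effect and once with the PE effect alone.

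The fits were tested on simulated data for 10537 genes with the observed means and spread, of which 200 were changed. For PE against vehicle, 82.1%, 97% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 14 unchanged genes called. For PE + miR-9 against PE the shares were 80.6%, 98.5% and 100% with 12 such calls when PE was changed, and 86.6%, 100% and 100% with 14 when PE + miR-9 was changed. For PE + miR-9 against vehicle they were 88.1%, 98.5% and 100%, with 7. With 1 list of 20 genes shifted by 0.5 in that last comparison, camera called this list and 0 of the others. The simulated genes varied independently of each other, so this does not show how camera does with correlated genes.

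Alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median scaling over genes with a mean FPKM of at least 10, quantile normalization, only the 2 groups compared, no variance trend, and leaving out each library. Quantile normalization gives each rank the same value in every library, so a gene that keeps its rank shows no change under it. Lists were run under the pseudocount, median, quantile and left-out-library alternatives and the other list tests. Scaling to the spike-ins was chosen after the data were seen: each library was divided by its median ratio over the 28 spike-ins with a mean FPKM of at least 20 and a value above 0 in every library, with all 8 libraries or with 7, without Vehicle replicate 3. Genes with seed matches to miR-9 were not tested, since no 3' UTRs were used here.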

Results

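Neonatal rat ventricular myocytes, heart muscle cells taken from newborn rats and kept in culture, were profiled by RNA-seq of poly(A)-selected RNA in 3 groups. Phenylephrine (PE), an agonist of alpha-1 adrenergic receptors that makes these cells grow by hypertrophy, was given at 10 µM for 48 h. There were 3 vehicle libraries, 2 PE libraries and 3 libraries from cells given a miR-9 mimic at 25 nM 24 h before PE (PE + miR-9). The protocol names a control mimic for cultures without miR-9, but no single sample is labelled with it. The series title concerns BRD4, a bromodomain protein that binds acetylated chromatin, its recruitment to super-enhancers and the suppression of that recruitment by a microRNA. The comparisons ask which transcripts changed with PE, and how miR-9 altered the PE state. Expression was given as FPKM for 16808 gene symbols without positions, and 10537 of these were tested. The absolute depth is unknown. The relative depth, read from the steps between low values, was 0.905 to 1.49 times that of Vehicle replicate 1. Libraries of one group correlated more closely across genes (Pearson r of log2 values from 0.9869 to 0.9947) than libraries of different groups (0.9673 to 0.9838). Genes are not independent replicates. The first principal component held 47.6% of the variance and set Vehicle apart from the other groups. Component 2 held 24.2% and set PE apart from PE + miR-9. The labels do not say that replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

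ERCC spike-ins, synthetic RNAs added to samples as a reference, were listed for 92 sequences and did not have the same level in every library. Their summed FPKM was 12439.6 in Vehicle replicate 3, against 48678 and 53609 in the other Vehicle libraries and 60433 to 77495 in the 5 libraries given PE. The deposited values hold the median gene near a log2 fold change of 0 in each comparison. Scaling to the spike-ins, chosen after the data were seen, moved that median to -0.954 in PE against Vehicle, 0.0388 in PE + miR-9 against PE and -0.917 in PE + miR-9 against Vehicle (the 8-library scaling). Without Vehicle replicate 3 the medians were -0.307, 0.0458 and -0.255 (the 7-library scaling). Directions below therefore hold relative to all genes, and the value is given where a gene called as deposited, or the median of a gene group, crossed 0 under either scaling. Ranges of adjusted p over the other settings leave these scalings out.

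**Figure D1:**
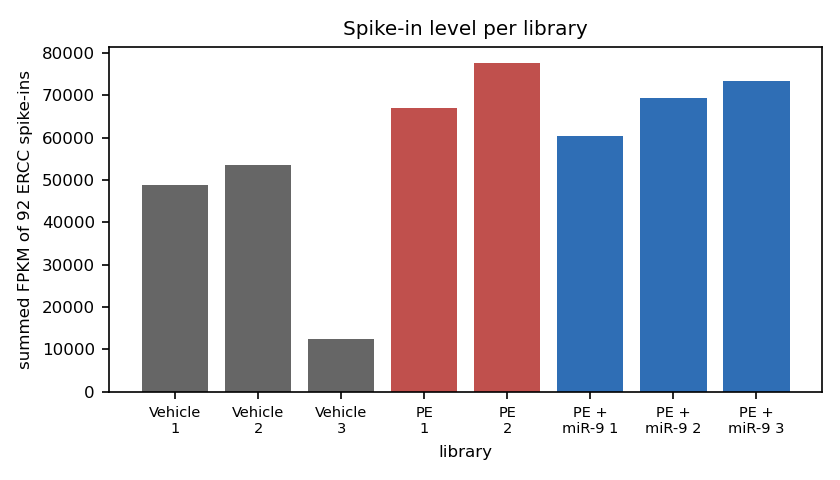
Summed FPKM of the 92 ERCC spike-ins (vertical axis) in each of the 8 libraries, 1 bar per library, coloured by group. Vehicle replicate 3 stands at 12439.6, below the other libraries, which lie between 48678 and 77495.

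PE against vehicle asks how cells without miR-9 responded to the hypertrophic stimulus. The natriuretic peptide gene Nppa rose from 2747 ± 306 (SD, n = 3) to 13041 ± 1194 (SD, n = 2) FPKM, and Nppb from 1705 ± 272 to 5585 ± 547 (adjusted p = 1.78e-05 and 4.01e-05). Xirp2, an actin-binding protein gene of the intercalated disc, rose from 20.8 ± 8.85 to 294 ± 0.772 FPKM. Acta1, the skeletal alpha-actin gene of the fetal programme, rose from 501 ± 78.3 to 1268 ± 129 (adjusted p = 4.51e-05 and 0.00018). Atp2a2, the calcium pump gene of the sarcoplasmic reticulum, fell from 858 ± 9.10 to 551 ± 7.94 FPKM, and Myh6, the alpha-myosin heavy chain gene, from 139.6 ± 9.90 to 86.6 ± 4.35 (adjusted p = 0.000285 and 0.000451).

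Of 13 tested hypertrophic and fetal genes, 12 rose and 1 fell (camera adjusted p = 1.97e-05; adjusted p = 0.577 with an estimated correlation). Among them were the LIM-domain gene Fhl1 and the nestin gene Nes, with log2 fold changes ± SE of 2.27 ± 0.17 and 1.80 ± 0.18 (adjusted p = 2.53e-05 and 7.94e-05). Rcan1, an inhibitor of calcineurin, changed by 1.10 ± 0.11 and the stretch-responsive gene Ankrd1 by 1.01 ± 0.087 (adjusted p = 9.78e-05 and 4.25e-05), with Ankrd1 at -0.017 under the 8-library scaling. Myh7, the beta-myosin heavy chain gene, changed by 0.22 ± 0.063 (adjusted p = 0.0155), and stood at -0.81 and -0.075 under the 8- and 7-library scalings. The Myh7 call ended without Vehicle replicate 2 (adjusted p = 0.0558) or PE replicate 1 (0.0984), within 0.0105 to 0.0984 over the other settings.

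**Figure D2:**
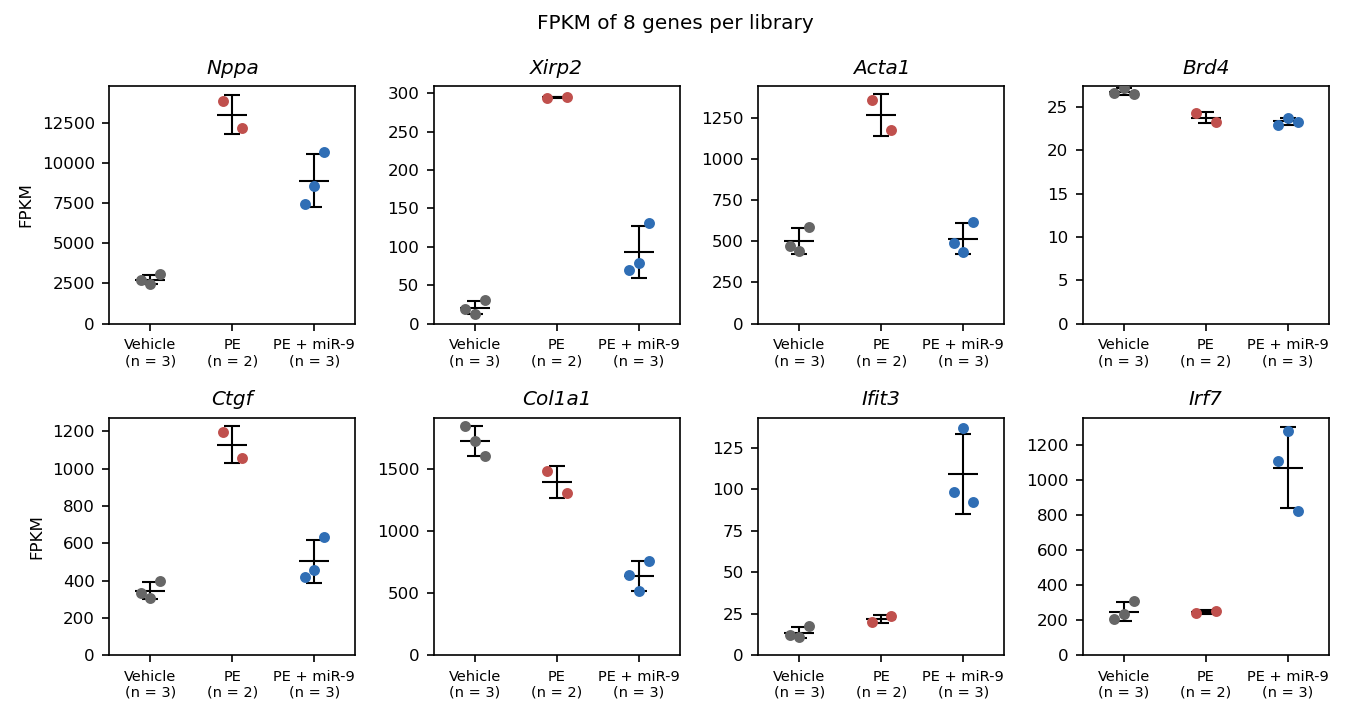
FPKM (vertical axes, from 0) of 8 genes in the Vehicle, PE and PE + miR-9 groups, with 1 point per library, the group mean as a horizontal bar and the SD as an error bar. Mean Nppa is 2747, 13041 and 8916 FPKM in the 3 groups, mean Ifit3 is 13.5, 21.9 and 109, and mean Brd4 is 26.8, 23.8 and 23.3.

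Of 24 immediate-early and MAPK feedback genes, 18 rose and 1 fell (camera adjusted p = 1.97e-05; adjusted p = 0.508 with an estimated correlation), the median of 0.454 becoming -0.536 under the 8-library scaling, 0.418 above that of all genes. They included the nuclear receptor gene Nr4a3 (1.59 ± 0.11), the stress transcription factor gene Atf3 (1.29 ± 0.14), Ier3 (1.15 ± 0.12) and the ERK phosphatase gene Dusp6 (1.07 ± 0.070), at adjusted p from 1.78e-05 to 0.000121. Of 26 cell-cycle genes, 1 rose and 24 fell (camera adjusted p = 5.17e-10; adjusted p = 0.577 with an estimated correlation). The mitotic kinesin gene Kif20a changed by -0.99 ± 0.10 and the cyclin gene Ccnb2 by -0.94 ± 0.092 (adjusted p = 7.07e-05 and 7.53e-05). Of 25 fatty acid oxidation genes, 1 rose and 13 fell (camera adjusted p = 0.00252; adjusted p = 0.577 with an estimated correlation). Hmgcs2, of ketone body synthesis, and the thiolase gene Acaa2 changed by -1.03 ± 0.11 and -0.62 ± 0.071 (adjusted p = 0.000131 and 0.000155). For oxidative phosphorylation, 2 rose and 14 fell of 26 genes (camera adjusted p = 0.0253; adjusted p = 0.664 with an estimated correlation). Mitochondrial creatine kinase, Ckmt2, stood at -1.21 ± 0.10 and the ATP synthase subunit gene Atp5o at -0.40 ± 0.064 (adjusted p = 3.81e-05 and 0.000866). That list's call ended without Vehicle replicate 3 (adjusted p = 0.0936) or PE replicate 2 (0.0605), within 3.31e-05 to 0.664 over the other settings. The 8- and 7-library scalings ended it too (0.259 and 0.19).

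Sarcomere, sterol, p53 and ribosome biogenesis genes rose relative to all genes in the values as deposited. Of 17 sarcomere genes, 10 rose and 1 fell (camera adjusted p = 0.0153; adjusted p = 0.577 with an estimated correlation), with medians of -0.821 and -0.081 under the 8- and 7-library scalings and 0 under quantile normalization. Quantile normalization gave 4 higher and 5 lower and ended the call (adjusted p = 0.803, within 0.00432 to 0.803 over the other settings). The desmin gene Des changed by 1.25 ± 0.10 and Pdlim5 by 0.91 ± 0.066 (adjusted p = 3.48e-05 and 2.45e-05), with Pdlim5 at -0.12 under the 8-library scaling. Of 17 cholesterol synthesis genes, 10 rose and 0 fell (camera adjusted p = 0.00326; adjusted p = 0.577 with an estimated correlation), with medians of -0.752 and -0.0643 under the scalings, 0.202 and 0.242 above all genes, and adjusted p = 0.0521 under the first. The sterol pathway enzyme genes Idi1 (0.92 ± 0.078) and Cyp51 (0.75 ± 0.060) rose (adjusted p = 3.98e-05 and 3.55e-05) and stood at -0.10 and -0.28 under the 8-library scaling. Of 14 p53 response genes, 12 rose and 1 fell (camera adjusted p = 0.00206; adjusted p = 0.508 with an estimated correlation), with a median of -0.625 under the 8-library scaling. Plk2 (1.10 ± 0.10) and Btg2 (0.90 ± 0.086) were the most changed (adjusted p = 6.53e-05 and 6.92e-05), and Btg2 stood at -0.12 under that scaling. Of 24 ribosome biogenesis genes, 10 rose and 1 fell (camera adjusted p = 0.0238; adjusted p = 0.577 with an estimated correlation), with medians of -0.88 and -0.171 under the 2 scalings, which ended the call (adjusted p = 0.424 and 0.329). Without PE replicate 1 this list had adjusted p = 0.0503, within 0.00797 to 0.577 over the other settings, which include quantile normalization (0.0624). The small nucleolar ribonucleoprotein gene Gar1 (0.40 ± 0.072) and Wdr43 (0.37 ± 0.053) rose (adjusted p = 0.00166 and 0.00052) but stood at -0.58 and -0.63 under the 8-library scaling.

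Receptor and ion channel genes went both ways with PE in the values as deposited. Of 15 adrenergic and G-protein genes, 6 rose and 4 fell (camera adjusted p = 0.846), with a median of -0.000888, a mean of 0.0642 and an upward test. Rgs2, a regulator of G-protein signalling, changed by 1.5 ± 0.11, and the receptor genes Adra1b and Adrb1 by -1.24 ± 0.063 and -0.94 ± 0.10. Adra1a, another alpha-1 receptor gene, changed by 0.94 ± 0.082 but stood at -0.030 under the 8-library scaling (adjusted p from 9.52e-06 to 8.62e-05). Of 22 calcium and ion handling genes, 3 rose and 9 fell, or 3 and 10 adjusted over the list alone (camera adjusted p = 0.14). The potassium channel genes Kcnip2 (-1.22 ± 0.11) and Kcnj11 (-0.97 ± 0.088) fell most (adjusted p = 6.31e-05 and 5.22e-05). Of 16 cardiac transcription factor genes, 3 rose and 5 fell (camera adjusted p = 0.199). Under the 7-library scaling 3 adrenergic, 0 calcium and ion handling and 0 cardiac transcription factor genes were higher, and 8, 14 and 12 were lower. Irx4, a ventricular homeobox gene, fell from 85.2 ± 3.99 to 28.7 ± 2.24 FPKM, and Gata6 changed by -0.54 ± 0.069 (adjusted p = 2.55e-05 and 0.00029). Brd4 changed by -0.16 ± 0.040 and Brd3 by -0.46 ± 0.045, while Brd2 stood at 0.10 ± 0.045 (adjusted p = 0.00783, 7.63e-05 and 0.0883). Without PE replicate 2 Brd4 had adjusted p = 0.058 (0.00322 to 0.058 over the other settings), and without Vehicle replicate 3 Brd2 had 0.0475 (0.0475 to 0.433).

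Matrix, inflammation and interferon lists were not called with PE as deposited, though single members changed. Of 26 matrix and TGF-beta genes, 10 rose and 2 fell (camera adjusted p = 0.14), with medians of -0.943 and -0.269 under the 8- and 7-library scalings. Ctgf, a matricellular protein gene, rose from 345 ± 46.5 to 1129.5 ± 99.1 FPKM, and Tgfb2 changed by 1.63 ± 0.093 (adjusted p = 7.76e-05 and 1.32e-05). The plasminogen activator inhibitor gene Serpine1 changed by 1.01 ± 0.10 (adjusted p = 7.43e-05), or -0.020 under the 8-library scaling. The periostin gene Postn stood at -0.13 ± 0.12 (adjusted p = 0.373), or -0.55 (adjusted p = 0.00204) under the 7-library scaling. Of 18 inflammation genes, 10 rose and 3 fell (camera adjusted p = 0.14), with medians of -0.618 and -0.0426 under the scalings, where its upward test against other genes passed (adjusted p = 0.0128 and 0.0321). The chemokine gene Ccl20 and the prostaglandin synthase gene Ptgs2 changed by 1.26 ± 0.24 and 1.09 ± 0.12 (adjusted p = 0.00215 and 0.000133). Of 26 interferon genes, 7 rose and 7 fell (camera adjusted p = 0.872), and Cxcl10 changed by 1.15 ± 0.20 (adjusted p = 0.00139). The interferon median of 0.0472 lay opposite to its downward test, and was -0.0282, -0.971 and -0.196 under quantile normalization and the 8- and 7-library scalings. Of 11 smooth muscle and pericyte markers, 2 rose and 6 fell (camera adjusted p = 0.273), with a median of -0.255 and a mean of 0.0362. The contractile gene Cnn1 (2.14 ± 0.15), Cspg4 (1.28 ± 0.092) and Smtn (-0.81 ± 0.083) changed most, at adjusted p from 2.25e-05 to 9.67e-05. None of 11 leukocyte markers passed (camera adjusted p = 0.639). Of 19 glycolysis genes, 9 rose and 5 fell (camera adjusted p = 0.249), with a median of 0.224 (-0.803 and -0.137 under the scalings) and a mean of -0.0195.

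Beyond these lists, the bradykinin B2 receptor gene Bdkrb2 rose from 2.23 ± 0.743 to 33.2 ± 1.64 FPKM. The sodium channel subunit gene Scn3b (2.83 ± 0.26), Pxdc1 (2.53 ± 0.18) and Tmeff1 (2.38 ± 0.14) followed, at adjusted p from 1.18e-05 to 5.22e-05 for the 4 genes. The sodium pump subunit gene Atp1a3 fell from 38.0 ± 2.17 to 6.64 ± 0.499 FPKM. Falls were also large in Dhrs7c (-1.95 ± 0.12), Doc2g (-1.88 ± 0.17), the muscle phosphoglycerate mutase gene Pgam2 (-1.85 ± 0.17) and Sorcs2 (-1.75 ± 0.13). The aldolase gene Aldoc (-1.74 ± 0.16), Gstm7 (-1.69 ± 0.17) and the imprinted noncoding RNA H19 (-1.66 ± 0.18) fell as well, with adjusted p from 6.83e-06 to 0.000136 for these 8 genes. MicroRNA genes were among the largest changes. Their values, here and in the other comparisons, may rest on single fragments in very short genes. Mir23a, Mir1949 and Mir31 were listed at 0 in every Vehicle library and at 34.2 and 36.4, 23.0 and 12.2, and 16.2 and 17.2 FPKM in the PE libraries. Mir301a and Mir3572 were also listed at 0 in Vehicle and at 10.2 and 10.8, and 7.54 and 8.02 FPKM in PE. Mir324 and Mir219-1 were listed at 0 in both PE libraries and at 31.8, 70.2 and 21.2, and 10.2, 11.3 and 6.81 FPKM in Vehicle. Leaving out PE replicate 2 ended the calls of Mir23a, Mir324 and Mir219-1 (adjusted p = 0.0551, 0.0514 and 0.058), leaving out PE replicate 1 that of Mir1949 (0.0607), and leaving out either those of Mir301a (0.0612 and 0.0749 without replicates 1 and 2) and Mir3572 (0.0816 and 0.099). Their lowest adjusted p over the other settings were 3.93e-09, 3.74e-05, 1.09e-05, 1.07e-05, 3.45e-07 and 9.07e-07 for Mir23a, Mir324, Mir219-1, Mir1949, Mir301a and Mir3572.

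In all, limma called 5676 of 10537 genes with PE, 2883 higher and 2793 lower, with 164 and 90 of them changed at least 2-fold. Group values did not overlap for 72.0% of genes, against 20% by chance. The split was 503 higher and 4657 lower under the 7-library scaling, and 8 higher and 14 lower under the 8-library scaling. Of the gene lists, 9 of 26 were called, none with an estimated correlation. Counts adjusted over the list alone were the same as those over all genes except where given.

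PE + miR-9 against PE shows what differed with the mimic in stimulated cells. No PE library is labelled with the control mimic, though the protocol names it for cultures without miR-9. If the PE cultures had it, both groups were transfected, and a response to any transfected RNA would be shared. As no label states this per sample, effects of miR-9 cannot be told apart with certainty from effects of any transfected RNA. Interferon-stimulated genes rose together, all 26 of 26 tested members being higher (camera adjusted p = 1.59e-16; adjusted p = 0.475 with an estimated correlation). Ifit3, an antiviral effector gene, rose from 21.9 ± 2.44 (SD, n = 2) to 109 ± 24.2 (SD, n = 3) FPKM. The antiviral GTPase gene Mx1 rose from 14.6 ± 0.976 to 73.3 ± 11.8 and the transcription factor gene Irf7 from 245 ± 10.8 to 1070.1 ± 231 (adjusted p = 0.00014, 0.000121 and 0.000159). Matrix genes fell: of 26 members, 23 were lower and 1 higher (camera adjusted p = 3.64e-09; adjusted p = 0.475 with an estimated correlation). The collagen gene Col1a1 went from 1399 ± 129 to 641 ± 120.4 FPKM and the fibrillin gene Fbn1 from 75.3 ± 2.34 to 25.0 ± 5.15 (adjusted p = 0.000498 and 0.000144). Several genes that PE had raised were lower again, with Acta1 at 516 ± 93.7 and Xirp2 at 93.0 ± 33.4 FPKM (adjusted p = 0.000467 and 0.0043).

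**Figure D3:**
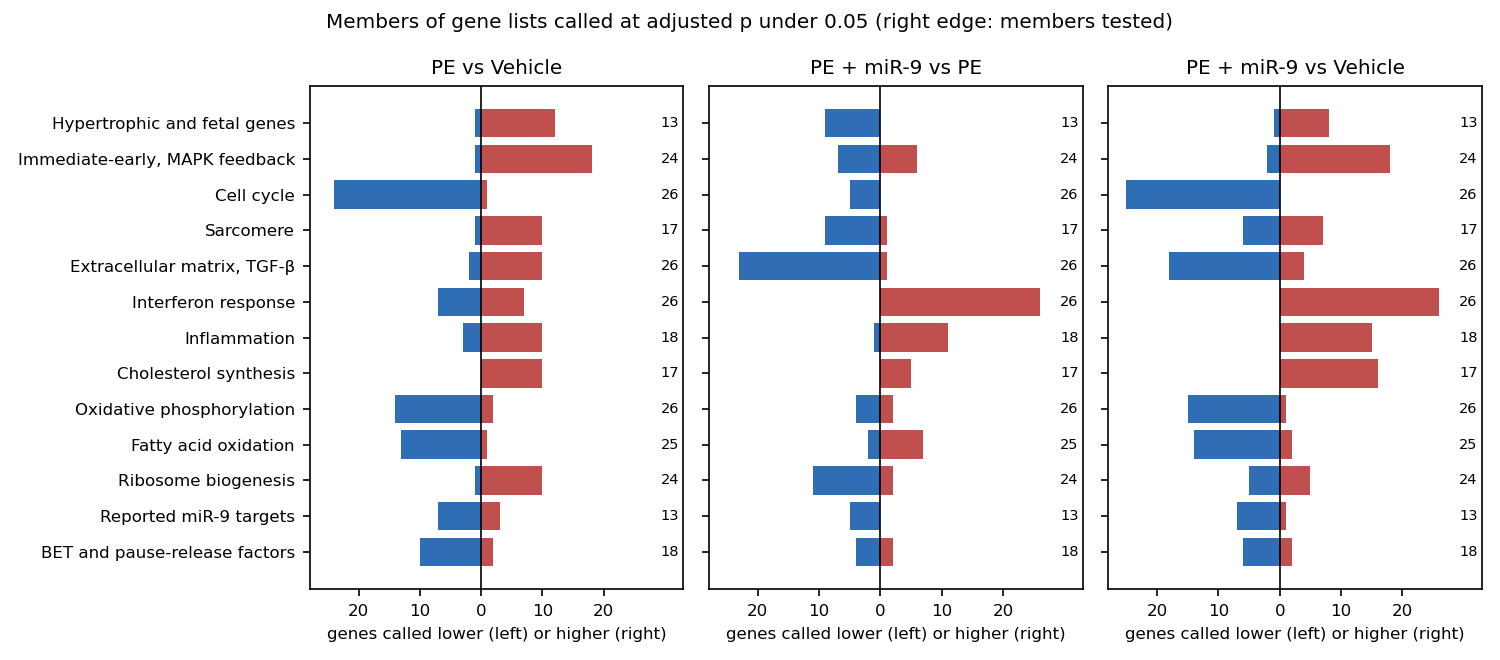
Number of members of 13 gene lists called lower (bars to the left) or higher (bars to the right) at an adjusted p under 0.05 in each comparison, as deposited, with the number tested at the right edge. In PE + miR-9 against PE all 26 interferon genes were called higher and 23 of 26 matrix genes lower, while the 8-library spike-in scaling left 0 of either called, with medians of 1.1 and -0.561.

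The interferon genes Oasl (2.13 ± 0.16), Cxcl10 (2.11 ± 0.20) and Rsad2 (1.95 ± 0.20) were also among the largest rises, at adjusted p from 6.41e-05 to 0.000224. Of 18 inflammation genes, 11 rose and 1 fell, or 13 and 1 adjusted over the list alone (camera adjusted p = 8.77e-06; adjusted p = 0.475 with an estimated correlation). They included the chemokine genes Ccl7 (1.49 ± 0.084), Cxcl12 (1.22 ± 0.087) and Ccl2 (1.04 ± 0.067) and the adhesion molecule gene Vcam1 (1.08 ± 0.083), at adjusted p from 3.09e-05 to 7.36e-05. The largest rise among called genes without overlap was in the chemokine gene Cxcl5, from 9.65 ± 3.58 to 65.0 ± 7.49 FPKM. Complement factor B, Cfb (2.43 ± 0.15), the chemokine gene Ccl5 (2.35 ± 0.26) and the interferon-induced GTPase gene Gbp2 (1.95 ± 0.14) came close to it, with adjusted p from 3.97e-05 to 0.000337 for the 4 genes.

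Markers of other cell types fell or split. Of 11 leukocyte markers, 0 rose and 6 fell, or 0 and 8 adjusted over the list alone (camera adjusted p = 0.0113; adjusted p = 0.62 with an estimated correlation). With fry the list had adjusted p = 0.0762. Cd53 stood at -0.77 ± 0.15 and Fcer1g at -0.71 ± 0.16 (adjusted p = 0.00481 and 0.00888). Without PE replicate 1 Fcer1g had adjusted p = 0.0618, within 0.00336 to 0.0618 over the other settings. Of 11 smooth muscle and pericyte markers, 1 rose and 6 fell (camera adjusted p = 0.0103; adjusted p = 0.475 with an estimated correlation). The contractile gene Tagln changed by -1.23 ± 0.11 and the growth factor receptor gene Pdgfrb by -0.74 ± 0.090 (adjusted p = 0.00014 and 0.000471). Of 8 epicardial markers, 0 rose and 4 fell (camera adjusted p = 0.0269; adjusted p = 0.475 with an estimated correlation), with Msln (-0.57 ± 0.14) and Krt18 (-0.42 ± 0.077) the most changed (adjusted p = 0.0132 and 0.00309). Without PE replicate 2 the epicardial list had adjusted p = 0.0804 and Msln 0.099, within 0.00553 to 0.475 and 0.000213 to 0.099 over the other settings. The call of the list ended also under the 8- and 7-library scalings (0.0959 and 0.0755). Of 14 fibroblast markers, 2 rose and 7 fell, or 2 and 8 adjusted over the list alone (camera adjusted p = 0.113). The decorin gene Dcn rose from 97.2 ± 0.702 to 203 ± 29.1 FPKM, while Mfap5 and Thy1 changed by -1.0 ± 0.12 and -0.75 ± 0.15 (adjusted p = 0.000155, 0.00044 and 0.00444). Pdgfra, the other marker that rose, changed by 0.51 ± 0.11 (adjusted p = 0.00557) and was named after its value was seen.

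Of 13 hypertrophic and fetal genes, 0 rose and 9 fell, or 1 and 11 adjusted over the list alone (camera adjusted p = 0.000731; adjusted p = 0.475 with an estimated correlation). Nes (-1.80 ± 0.18), Xirp2 (-1.71 ± 0.33), Acta1 (-1.31 ± 0.16) and Sertad4 (-0.71 ± 0.088) fell most, at adjusted p from 0.00019 to 0.0043. Nppa changed by -0.56 ± 0.15 (adjusted p = 0.016), a call that ended without PE replicate 1 (0.101) and under quantile normalization (0.108), within 0.00248 to 0.108 over the other settings. Ankrd1 changed by -0.39 ± 0.087 (adjusted p = 0.00786), with 0.362 under quantile normalization, within 0.00293 to 0.362. Nppb (-0.33 ± 0.15), Rcan1 (-0.27 ± 0.11), Myh7 (-0.16 ± 0.063) and Myh6 (0.067 ± 0.10) did not pass (adjusted p = 0.1, 0.0839, 0.0665 and 0.601). Nppb passed without PE + miR-9 replicate 3 (adjusted p = 0.0375, within 0.0375 to 0.66) and Rcan1 without Vehicle replicate 3 (0.0479, within 0.0479 to 0.341). Within the matrix list Ctgf fell from 1129.5 ± 99.1 to 503 ± 115 FPKM, Serpine1 changed by -1.06 ± 0.10 and Postn by -0.74 ± 0.12 (adjusted p = 0.00101, 0.000154 and 0.00166). Of 17 sarcomere genes, 1 rose and 9 fell (camera adjusted p = 0.00557; adjusted p = 0.475 with an estimated correlation), with a median of 0 under quantile normalization, which ended the call (0.404, within 0.00247 to 0.475 over the other settings). The M-band gene Myom2 and the troponin C gene Tnnc1 changed by -0.95 ± 0.094 and -0.55 ± 0.072 (adjusted p = 0.000199 and 0.000665), with Tnnc1 at 0.454 under quantile normalization, within 0.000244 to 0.454. The calcium pump gene Atp2a2 rose by 0.40 ± 0.082 (adjusted p = 0.00559).

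Amino acid and unfolded protein stress genes and ribosome biogenesis genes fell in the values as deposited. Of 22 genes of the first list, 1 rose and 12 fell (camera adjusted p = 0.00303; adjusted p = 0.475 with an estimated correlation). Under the 8- and 7-library scalings its call ended (adjusted p = 0.0959 and 0.0755), as did that of ribosome biogenesis (0.21 and 0.181). The cystine transporter gene Slc7a11 (-0.59 ± 0.086), Trib3 (-0.43 ± 0.081) and the serine synthesis gene Psat1 (-0.41 ± 0.055) changed most, at adjusted p from 0.000715 to 0.00349. Of 24 ribosome biogenesis genes, 2 rose and 11 fell, or 3 and 11 adjusted over the list alone (camera adjusted p = 0.00557; adjusted p = 0.475 with an estimated correlation). Nucleophosmin, Npm1, stood at -0.54 ± 0.051 and Gar1 at -0.32 ± 0.072 (adjusted p = 0.000166 and 0.00822). Without PE replicate 2 Gar1 had adjusted p = 0.0533, within 0.00329 to 0.0533 over the other settings. Of 17 cholesterol synthesis genes, 5 rose and 0 fell, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.0814). That list passed under quantile normalization (0.0165) and without PE + miR-9 replicate 2 (0.0217), within 0.0165 to 0.62.

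Brd4, a reported miR-9 target and the subject of the series title, did not differ detectably at the RNA level, at 23.8 ± 0.681 (SD, n = 2) FPKM in PE and 23.3 ± 0.419 (SD, n = 3) in PE + miR-9. Its log2 fold change was -0.026 (95% interval -0.12 to 0.064, adjusted p = 0.625). Brd3 changed by -0.18 ± 0.045 and Brd2 stood at -0.020 ± 0.045 (adjusted p = 0.0125 and 0.753). Without PE replicate 2 Brd3 had adjusted p = 0.0773, within 0.00863 to 0.0773 over the other settings, and it had 0.63 under the 7-library scaling. Of 18 BET and pause-release genes, 2 rose and 4 fell (camera adjusted p = 0.391), with a median of -0.023, and 0.0182 and 0.0249 under the 8- and 7-library scalings. Larp7, which keeps the elongation kinase P-TEFb inactive, changed by -0.54 ± 0.076 and the elongation factor gene Supt5h by 0.21 ± 0.051 (adjusted p = 0.000943 and 0.0108), with Supt5h at 0.0725 without PE replicate 2, within 0.00334 to 0.0725. Of 13 reported miR-9 targets, 0 rose and 5 fell (camera adjusted p = 0.113). Socs5 (-0.46 ± 0.049), Myocd (-0.43 ± 0.070), Stmn1 (-0.35 ± 0.075) and Map1b (-0.23 ± 0.061) and, named after its value was seen, Rest (-0.23 ± 0.054) were those called, at adjusted p from 0.000258 to 0.0165. Without PE replicate 2 Map1b had adjusted p = 0.122 and Rest 0.0737, within 0.0122 to 0.122 and 0.00526 to 0.0737 over the other settings. The 7-library scaling left 2 targets lower and 0 higher, ending the calls of Stmn1 (adjusted p = 0.155), Map1b (0.464) and Rest (0.461).

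Of 16 cardiac transcription factor genes, 8 rose and 3 fell, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.113). Irx4 stood at 74.1 ± 11.7 FPKM, above PE, and Nfatc2 changed by 0.53 ± 0.083 (adjusted p = 0.000115 and 0.00161). Of 22 calcium and ion handling genes, 7 rose and 2 fell (camera adjusted p = 0.171), with the gap junction gene Gja1 at 0.60 ± 0.093 and Kcnj11 at 0.57 ± 0.088 (adjusted p = 0.00146 and 0.00146). Of 15 adrenergic and G-protein genes, 6 rose and 1 fell (camera adjusted p = 0.148), with Adra1b at 0.65 ± 0.063 and Adrb1 at 0.64 ± 0.10 (adjusted p = 0.000178 and 0.00125). The remaining large falls were in the pigment epithelium-derived factor gene Serpinf1 (-1.80 ± 0.16), Cthrc1 (-1.38 ± 0.091), the calsequestrin gene Casq1 (-1.26 ± 0.13) and Emp1 (-1.24 ± 0.082), at adjusted p from 4.18e-05 to 0.000208. Mir27a and the histone gene Hist1h1d were listed at 0 in every PE + miR-9 library and at 35.9 and 19.1, and 8.41 and 26.8 FPKM in PE. The Mir27a call ended without PE replicate 1 (adjusted p = 0.0812) or 2 (0.0595), within 4.18e-05 to 0.0812 over the other settings. That of Hist1h1d ended without PE replicate 1 (0.0604) or 2 (0.194), without PE + miR-9 replicate 1 (0.0622), 2 (0.0592) or 3 (0.0515) and with no filter (0.0633), within 0.00117 to 0.194.

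In all, limma called 4348 of 10537 genes with miR-9, 2196 higher and 2152 lower, 95 and 35 of them changed at least 2-fold. Group values did not overlap for 62.5% of genes, against 20% by chance. Without PE replicate 2 there were 2388 calls. There were 905 higher and 547 lower under the 7-library scaling, and 2 higher and 8 lower under the 8-library scaling.

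PE + miR-9 against vehicle shows what differed from unstimulated cells when both treatments were given. The chemokine genes Cxcl5 and Cxcl10 were far above vehicle, Cxcl5 at 65.0 ± 7.49 (SD, n = 3) against 4.65 ± 0.851 (SD, n = 3) FPKM and Cxcl10 at 199 ± 46.2 against 19.8 ± 4.41 (adjusted p = 2.33e-06 and 3.86e-06). Nppa (1.69 ± 0.13), Nppb (1.39 ± 0.13), Xirp2 (2.13 ± 0.30) and Fhl1 (1.71 ± 0.15) stayed above vehicle, at adjusted p from 1.77e-05 to 0.000359. Acta1 and Serpine1 did not differ detectably from it (0.039 ± 0.14 and -0.056 ± 0.088; adjusted p = 0.831 and 0.611). Of 26 cell-cycle genes, 0 rose and 25 fell (camera adjusted p = 1.04e-11; adjusted p = 0.455 with an estimated correlation), with Ccnb2 at -1.08 ± 0.082 and the proliferation marker gene Mki67 at -1.02 ± 0.070 (adjusted p = 1.53e-05 and 1.03e-05).

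Of 26 interferon genes all 26 rose (camera adjusted p = 8.58e-12; adjusted p = 0.455 with an estimated correlation), though the median of 0.925 was -0.0387 under the 8-library scaling, 0.878 above that of all genes. Of 18 inflammation genes, 15 rose and 0 fell, or 16 and 0 adjusted over the list alone (camera adjusted p = 5.78e-07; adjusted p = 0.369 with an estimated correlation), with Ccl20 at 2.21 ± 0.21 and Ccl7 at 1.76 ± 0.075 (adjusted p = 4.68e-05 and 1.31e-06). Of 13 hypertrophic and fetal genes, 8 rose and 1 fell (camera adjusted p = 0.0138; adjusted p = 0.551 with an estimated correlation), the median of 0.625 being -0.363 under the 8-library scaling, 0.554 above all genes. Rcan1 (0.83 ± 0.10), Ankrd1 (0.63 ± 0.078) and Ctgf (0.52 ± 0.15) rose (adjusted p = 0.000177, 0.000185 and 0.0161) but stood at -0.16, -0.36 and -0.46 under that scaling. Without Vehicle replicate 2 Ctgf had adjusted p = 0.0609, within 0.00672 to 0.0609 over the other settings. Myh6 (-0.61 ± 0.085), Atp2a2 (-0.24 ± 0.073) and Postn (-0.88 ± 0.11) fell (adjusted p = 0.000344, 0.019 and 0.000153), and Myh7 stood at 0.060 ± 0.057 (adjusted p = 0.391). Atp2a2 had adjusted p = 0.171 under quantile normalization and 0.0535 without Vehicle replicate 1, within 0.00259 to 0.171, and Myh7 had 0.0228 under quantile normalization, within 0.0228 to 0.79. Of 17 cholesterol synthesis genes, 16 rose and 0 fell (camera adjusted p = 2.13e-06; adjusted p = 0.455 with an estimated correlation), with a median of -0.606 under the 8-library scaling. Idi1 (0.93 ± 0.069) and Sqle (0.69 ± 0.046) rose most (adjusted p = 1.47e-05 and 8.91e-06), and stood at -0.055 and -0.29 under that scaling. Of 24 immediate-early genes, 18 rose and 2 fell (camera adjusted p = 1.73e-05; adjusted p = 0.369 with an estimated correlation), with a median of -0.494 under the 8-library scaling. The nuclear receptor genes Nr4a3 (1.39 ± 0.10) and Nr4a1 (1.13 ± 0.10) rose most (adjusted p = 1.14e-05 and 3.2e-05). Of 14 p53 response genes, 8 rose and 1 fell (camera adjusted p = 0.0362; adjusted p = 0.455 with an estimated correlation), with a median of -0.746 under the 8-library scaling. That call ended without Vehicle replicate 2 (adjusted p = 0.0646) or PE + miR-9 replicate 3 (0.0522) and under quantile normalization (0.0575), within 0.00183 to 0.455 over the other settings. It ended under the 8- and 7-library scalings too (0.175 and 0.0767). The cell-cycle inhibitor gene Cdkn1a and Plk2 changed by 0.90 ± 0.078 and 0.61 ± 0.093 (adjusted p = 2.85e-05 and 0.00057), but stood at -0.086 and -0.37 under the 8-library scaling. Rgs2 changed by 1.99 ± 0.094 (adjusted p = 1.9e-06).

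Matrix genes lay below vehicle. Of 26 members, 4 rose and 18 fell, or 5 and 18 adjusted over the list alone (camera adjusted p = 0.00227; adjusted p = 0.551 with an estimated correlation), with Fbn1 at -1.56 ± 0.13 and Col1a1 at -1.45 ± 0.12 (adjusted p = 2.25e-05 and 2.76e-05). Of 26 oxidative phosphorylation genes, 1 rose and 15 fell (camera adjusted p = 0.00447; adjusted p = 0.551 with an estimated correlation), with Ckmt2 at -2.07 ± 0.090 and Cox4i1 at -0.36 ± 0.054 (adjusted p = 1.32e-06 and 0.000575). Of 25 fatty acid oxidation genes, 2 rose and 14 fell, or 3 and 14 adjusted over the list alone (camera adjusted p = 0.0107; adjusted p = 0.551 with an estimated correlation), with Hmgcs2 at -1.46 ± 0.10 and the fatty acid transporter gene Cd36 at -0.41 ± 0.070 (adjusted p = 1.09e-05 and 0.00104). The calls of these 2 lists ended under the 8- and 7-library scalings (adjusted p = 0.0769 and 0.0572 for oxidative phosphorylation, 0.0605 and 0.0572 for fatty acid oxidation). Of 13 reported miR-9 targets, 1 rose and 7 fell (camera adjusted p = 0.0138; adjusted p = 0.369 with an estimated correlation), with the microtubule regulator gene Stmn1 at -1.32 ± 0.067 and the chemokine receptor gene Cxcr4 at -0.66 ± 0.11 (adjusted p = 2.75e-06 and 0.00081). In PE against vehicle, without miR-9, 3 of these targets rose and 7 fell (camera adjusted p = 0.192). The median was -0.164 there and -0.19 here, and the mean -0.134 and -0.281. Between PE + miR-9 and PE the targets had a median of -0.156, with 0 higher and 5 lower (camera adjusted p = 0.113). How much of the fall against vehicle goes with miR-9 is therefore not settled. Brd4 (-0.19 ± 0.036) and Brd3 (-0.64 ± 0.040) were lower than in vehicle, and Brd2 stood at 0.081 ± 0.040 (adjusted p = 0.00187, 6.81e-06 and 0.117). Of 11 leukocyte markers, 0 rose and 8 fell (camera adjusted p = 0.0099; adjusted p = 0.551 with an estimated correlation), with Fcer1g at -0.86 ± 0.15 and Tyrobp at -0.71 ± 0.22 (adjusted p = 0.00103 and 0.0213). The Tyrobp call ended without Vehicle replicate 1 (adjusted p = 0.0622) or PE + miR-9 replicate 1 (0.0529) or 2 (0.0704), within 0.00526 to 0.0704 over the other settings. Of 11 smooth muscle and pericyte markers, 2 rose and 8 fell (camera adjusted p = 0.0201; adjusted p = 0.551 with an estimated correlation), with Cnn1 at 1.55 ± 0.14 and Tagln at -1.43 ± 0.10 (adjusted p = 3.23e-05 and 1.1e-05).

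Of the lists not called here, heat shock and oxidative stress had 8 higher and 2 lower of 17 (camera adjusted p = 0.0633), with medians of -0.744 and -0.0453 under the 8- and 7-library scalings. Fibroblast markers had 3 higher and 9 lower of 14 (camera adjusted p = 0.0633). Both lists passed without Vehicle replicate 3 (adjusted p = 0.033 and 0.0328) or PE + miR-9 replicate 1 (0.0389 and 0.0363), and the fibroblast list without PE + miR-9 replicate 3 (0.042), within 0.00225 to 0.551 and 0.0328 to 0.551 over the other settings. The fibroblast list passed downward under the 8- and 7-library scalings as well (0.0166 and 0.00425). Endothelial markers had 3 higher and 1 lower of 4 (camera adjusted p = 0.58), with a median of 0.325, and -0.474 under the 8-library scaling. Schwann and neural markers had 2 higher and 2 lower of 5 (camera adjusted p = 0.966), with a median of -0.2 opposite to the direction of the test. The other largest rises were in Ccl5 (3.08 ± 0.24), Bdkrb2 (3.06 ± 0.17) and Ifit3 (2.93 ± 0.18), the protease inhibitor gene Slpi (2.77 ± 0.10), and Gbp2 (2.77 ± 0.13), Mx1 (2.67 ± 0.17), Oasl (2.65 ± 0.14) and Rsad2 (2.55 ± 0.18), at adjusted p from 6.95e-07 to 1.56e-05. The other largest falls were in Atp1a3 (-2.73 ± 0.081), Dhrs7c (-1.96 ± 0.11), Serpinf1 (-1.78 ± 0.14), Akr1cl (-1.73 ± 0.061), Pgam2 (-1.72 ± 0.15), Plac9 (-1.65 ± 0.15) and Smim5 (-1.63 ± 0.11) and the collagen prolyl hydroxylase gene P4ha2 (-1.58 ± 0.063), at adjusted p from 4.76e-07 to 3.56e-05. Mir628 was listed at 30.2, 33.4 and 80.8 FPKM in Vehicle and at 0, 0 and 20.8 in PE + miR-9. Its call (adjusted p = 0.0321) ended without Vehicle replicate 1 (0.058), 2 (0.0637) or 3 (0.0882), without PE + miR-9 replicate 1 (0.0968) or 2 (0.1) and with no filter (0.064), within 0.00282 to 0.1 over the other settings.

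In all, limma called 5877 of 10537 genes between PE + miR-9 and vehicle, 2992 higher and 2885 lower, 210 and 100 of them changed at least 2-fold. Group values did not overlap for 64.8% of genes, against 10% by chance. There were 692 higher and 4268 lower under the 7-library scaling, and 6 higher and 28 lower under the 8-library scaling.

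Many genes that PE changed differed the other way between PE + miR-9 and PE. Of 2883 genes higher with PE, 1183 (41.0%) were lower in PE + miR-9 than in PE and 258 were higher. Of 2793 genes lower with PE, 1085 (38.9%) were higher and 219 lower. Among the first were Acta1 (1.35 with PE, then -1.31 with miR-9), Serpine1 (1.01, then -1.06), Nes (1.80, then -1.80) and Ctgf (1.71, then -1.19). Irx4 (-1.54, then 1.33) and Atp2a2 (-0.64, then 0.40) were among the second. Over all genes called with PE, a median of 63.7% of the PE change was left in PE + miR-9, at 54.2%, 68.5% and 67.8% in its libraries (mean 63.5% ± 8.06, SD, n = 3). Both comparisons use the same 2 PE libraries, too few to give each comparison 2 of its own, so part of the excess may come from them. Their summed gene FPKM was 747967 and 719867, against 670234 to 688742 in the other libraries. Their relative depths of 1.45 and 1.36 lay above all but Vehicle replicate 3 (1.49) and PE + miR-9 replicate 3 (1.46). A technical trait of the PE libraries would give opposite changes in the 2 comparisons. Median scaling gave counts of 1041 and 1219 in the 2 directions, while depth was not tested. Simulated groups with the PE change and no miR-9 effect gave at most 1 gene in either direction over 100 draws and left 97.6% of the change. In these draws PE + miR-9 differed from PE by noise alone, so few calls were bound to follow. They cannot show whether the changes with miR-9 run against those with PE. Independent lists of these sizes would share 588.8 and 582.1 genes. The covariance of the log2 fold changes was -0.0585, against -0.0158 in simulated groups with no effect, a difference of -0.0427. The correlation was -0.422, against -0.581 in those groups. With 1 PE library in each comparison, a split chosen after the data were seen, the counts were 697 and 624, or 605 and 526 with the libraries exchanged. Independent lists would then share 339.5 and 330, or 292.1 and 268.7, and the covariance was -0.0517 or -0.0468. The counts were 587 and 477 without PE replicate 2, 184 and 583 under the 7-library scaling, and 4 and 0 under the 8-library scaling.

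**Figure D4:**
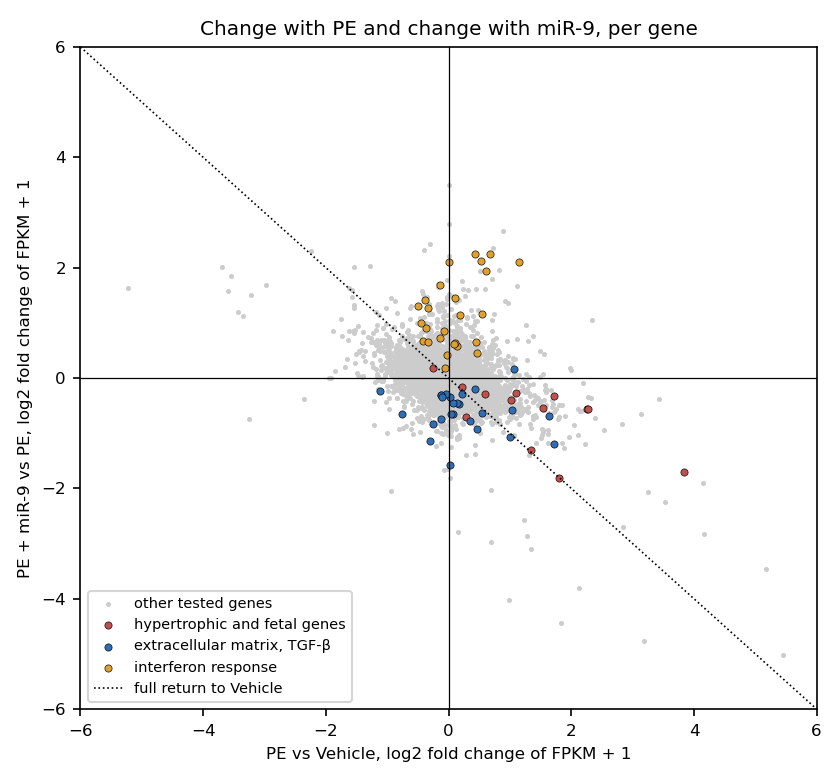
Log2 fold change of FPKM + 1 with PE (horizontal axis, PE against Vehicle) and with miR-9 (vertical axis, PE + miR-9 against PE) for 10537 tested genes as deposited, 1 point per gene, with 3 gene lists coloured and a dotted line where miR-9 would cancel the PE change. Of 2883 genes higher with PE, 1183 were lower again with miR-9, and all 26 interferon genes lie above 0 on the vertical axis, though none is called under the 8-library spike-in scaling.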

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

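The spike-in comparison was chosen after the data were seen. The ERCC spike-ins are outside the gene comparisons and stood higher in the groups given PE than in vehicle. Their summed FPKM averaged 72198 ± 7491 (SD, n = 2) in PE and 67639 ± 6553 (SD, n = 3) in PE + miR-9, against 38242 ± 22481 (SD, n = 3) in Vehicle. Vehicle replicate 3 had 12439.6, and the mean of the other Vehicle libraries was 51144. Of 92 spike-ins, 70 were above 0 in all libraries. Over the 28 used for scaling, Vehicle replicate 1 stood at 4.0 times Vehicle replicate 3. The amount of spike-in added per library or per cell is not given in the sources used here, and no explanation of the difference was tested.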

How the results depend on the processing

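Scaling to the spike-ins and the split of the PE libraries, 1 to each comparison, were chosen after the data were seen. The other alternatives were planned. Without 1 library, genes called in PE + miR-9 against PE ranged from 2388 (without PE replicate 2) to 4181 (without PE + miR-9 replicate 3). Genes higher with PE and lower with miR-9 ranged from 587 (without PE replicate 2) to 1121 (without Vehicle replicate 3), and genes lower with PE and higher with miR-9 from 477 (without PE replicate 2) to 1081 (without PE + miR-9 replicate 3). With PE library 1 set against vehicle and PE library 2 against PE + miR-9 these counts were 697 and 624, and with the 2 libraries exchanged 605 and 526. Leaving out a PE library leaves 1, which is assumed to vary like the other groups. With an estimated correlation 0, 0 and 0 lists were called in PE against vehicle, PE + miR-9 against PE and PE + miR-9 against vehicle, where camera called 9, 10 and 13. fry, a different question, called 18, 15 and 21. Outside the spike-in scalings, no gene named in the report and called turned its direction, and calls that ended are given there with their gene or list. Of the genes named only in the observations, Mt1a, Mt2A and Nqo1 were run under these alternatives and kept their calls outside the spike-in scalings. The others named only there were not run. Glycolysis in PE + miR-9 against PE passed under quantile normalization (adjusted p = 0.0103). Quantile normalization ended the calls of 4 and gave that of 1 of the 199 named values, and no filter ended 2. Median scaling, a pseudocount of 0.1, no trend and only the compared groups changed none, nor did a mean FPKM of at least 5 for the 182 it tests.

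With 8-library spike-in scaling 22, 10 and 34 genes were called in the 3 comparisons, the reversal counts were 4 and 0, and 17 named values turned, 150 lost their call and 32 stayed on their side. The loss follows from the factor of 4.0 between Vehicle replicates 1 and 3, which widens the shared spread. Log2 fold changes that turned in PE against vehicle were Myh7 -0.8062, Ankrd1 -0.01676, Serpine1 -0.01958, Pdlim5 -0.1209, Adra1a -0.0295, Gar1 -0.5787, Wdr43 -0.6309, Idi1 -0.1018, Cyp51 -0.2818 and Btg2 -0.1238. In PE + miR-9 against vehicle they were Rcan1 -0.1571, Ankrd1 -0.3634, Ctgf -0.463, Idi1 -0.05546, Sqle -0.2941, Cdkn1a -0.08567 and Plk2 -0.3675. With 7 libraries Myh7 was -0.0746 in PE against vehicle, 1452 genes were called in PE + miR-9 against PE, the reversal counts were 184 and 583, and 76.44% of the PE change was left. There 1 named value turned, 11 lost and 1 gained a call. The calls lost were Gar1 (adjusted p = 0.569) and Wdr43 (0.624) in PE against vehicle, and in PE + miR-9 against PE Brd3 (0.63), Ankrd1 (0.109), Gar1 (0.208), Supt5h (0.245), Stmn1 (0.155), Map1b (0.464), Psat1 (0.0671), Krt18 (0.0577) and Rest (0.461). Called genes were higher in 9.75%, 62.3% and 14% of cases with 7 libraries, against 50.8%, 50.5% and 50.9% as deposited. Why spike-ins and genes disagree was not tested.

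No paired analysis was possible because the labels tie no replicate of one group to a replicate of another. The test of miR-9 seed sites was not run, for want of 3' UTRs. Genes of low FPKM rest on few fragments, and depth differed up to 1.49-fold against Vehicle replicate 1.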

Other observations

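The lists in this paragraph and its genes were chosen after the data were seen. Ribosomal protein genes were lower in PE + miR-9 than in PE, 63 of 74 called lower and 0 higher, or 65 and 0 adjusted over the list alone (camera adjusted p = 8.06e-22; adjusted p = 0.0747 with an estimated correlation). Rps6, of the small subunit, went from 1351 ± 8.38 (SD, n = 2) to 857 ± 33.9 (SD, n = 3) FPKM (adjusted p = 4.97e-05). Quantile normalization gave 46 lower and 1 higher, and the 7-library spike-in scaling 12 lower and 0 higher. Antigen presentation genes were higher, 22 of 23 with 0 lower (camera adjusted p = 1.14e-13; adjusted p = 0.0747 with an estimated correlation). B2m, the light chain of class I molecules, rose from 951 ± 7.78 to 1801 ± 219.6 FPKM and the peptide transporter gene Tap2 changed by 0.82 ± 0.066 (adjusted p = 0.000467 and 8.65e-05). Of 16 complement genes, 10 were higher and 1 lower (camera adjusted p = 3.72e-05; adjusted p = 0.05 with an estimated correlation), with the inhibitor gene Serping1 at 1.64 ± 0.073 and C2 at 1.47 ± 0.059 (adjusted p = 1.09e-05 and 7.48e-06). Against vehicle, 73 ribosomal protein genes were lower and 0 higher, or 74 and 0 adjusted over the list alone, and 21 antigen presentation genes higher (median 0.887, but -0.0155 under the 8-library spike-in scaling). Of the complement genes 10 were higher and 1 lower there, or 11 and 2 adjusted over the list alone, with a median of 0.369, but -0.566 under that scaling. These 3 lists had camera adjusted p = 1.59e-22, 2.16e-09 and 0.000877, and adjusted p = 0.107, 0.11 and 0.107 with an estimated correlation. With PE alone 7 ribosomal protein genes were higher and 24 lower (6 and 22 over the list alone), 1 and 6 antigen presentation genes (1 and 5 over the list alone), and 1 and 3 complement genes (camera adjusted p = 0.0723, 0.283 and 0.283). The metallothionein genes Mt1a (1.30 ± 0.077) and Mt2A (1.29 ± 0.066) rose and the oxidoreductase gene Nqo1 (-1.11 ± 0.090) fell with miR-9 (adjusted p = 3.66e-05, 2.25e-05 and 8.93e-05).

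In the paragraphs on interferon, matrix and microRNA genes, median and quantile scaling were planned, while spike-in scaling and the other tests were chosen after the results were seen. What the counts of called members under library scaling would mean was written before those counts were seen. The counts over splits of the libraries were planned.

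Interferon genes were higher in PE + miR-9 than in PE. Under median, quantile and 8-library spike-in scaling 26, 26 and 0 members were called, and 25 without Vehicle replicate 3; by the counts fixed beforehand the 0 met the prediction for library scaling as the cause. That reading was set aside after the count was seen, and scaling left open by it, because the median change went from 1.07 to 1.1 while the median SE went from 0.104 to 0.777, through a Vehicle library outside the comparison. By size, the lowest median over the 4 scalings was 1.05. These scalings put the median of all genes in this comparison between -0.00586 and 0.0458, so little change in the list's median was bound to follow. Shifts of that size do not account for the rise, and the test says no more about scaling. Of the leukocyte markers 6 were lower with 0 higher, which argues against more leukocytes. A response to transfected RNA of any sequence would be shared if the PE cultures had the control mimic that the protocol names. The labels do not say which PE cultures had it, and 0 libraries are labelled as given no mimic. Such a response therefore cannot be told apart with certainty from one to miR-9. Both remain hypotheses.

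Matrix genes were lower in PE + miR-9 than in PE. The count under scaling was again 0 with 8 libraries and 17 with 7, where at least 18 had been asked for, with 23 and 20 under median and quantile scaling. With 8 libraries the median went from -0.604 to -0.561 and its SE from 0.0948 to 0.788, so the count of 0 was set aside for the same reason. This reason does not cover the 17 with 7 libraries, a scaling that leaves out Vehicle replicate 3. By size, the median nearest to 0 over the 4 scalings was -0.555. As for the interferon genes, these scalings hardly moved the median of all genes, so this was bound to stay near -0.604. Shifts of that size do not account for the fall, and the test says no more about scaling. Fewer fibroblasts as the whole cause, with expression per cell unchanged, would lower all fibroblast markers. But 2 were higher, Dcn (1.04 ± 0.10) and Pdgfra (0.51 ± 0.11), and Ddr2 and Tcf21 stood at -0.032 ± 0.069 and 0.12 ± 0.12. As 7 were lower, a part of the change may still come from fewer such cells. Whether the expression per cell changed was not tested. A reversal of the PE response alone is argued against by 15 members that were lower than in vehicle too and had not been called higher with PE, and an effect of miR-9 on matrix genes stays a hypothesis.

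MicroRNA genes were among the largest changes, with 17 of 53 tested called in some comparison. With each library set to 1 relative depth, 47 of 54 further nonzero values of the called genes (87.0%) were whole multiples of the gene's smallest nonzero value, within 2%, with a median highest multiple of 2, against 5.99% of 29435 values in 4206 other called genes with a mean FPKM under 20. Of the 17 genes, 7 had a highest multiple of 1. With a highest multiple of at least 2, within the tolerance, the shares were 83.7% of 43 values in 10 microRNA genes and 9.18% of 15274 values in 2183 other genes. The values of such genes may therefore rest on single fragments in very short genes, which the table cannot settle without counts, and no biological explanation was tested. Libraries that hold the same multiple have almost no spread between them, so small adjusted p of such genes may reflect these steps.

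The 6 PE + miR-9 and Vehicle libraries can be split into 3 and 3 in 10 ways, of which 1, the real one, called 5877 genes. The highest of the others called 4. These splits are too few for a share under 0.05.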
